A study of Mus musculus with 2 samples.

How the data were processed

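The data were 2 single-cell libraries of sorted mouse colon cells, 1 control and 1 from mice with a skin wound, made with the 10x Genomics Single Cell 3' chemistry, which counts unique molecular identifiers (UMIs) at the 3' end of polyadenylated RNA, per the labels' protocols. Tissue was digested with collagenase and DNase I and the cells were stained for viability, CD45 and PDGFRA before sorting, per the labels' protocols. Per the submitters' processing notes, the authors used Cell Ranger 3.0.1, Seurat 3 and the mouse build mm10. Per the labels, the libraries were aggregated with Cell Ranger. Whether reads were subsampled to equal depth at that step, how cells were filtered and how doublets were treated are not given in the sources used here. The deposited table holds raw UMI counts for 14767 genes in 1629 cells, and the authors' deposited metadata give, per the file headers, each cell's library, UMI count, number of detected genes, mitochondrial percent and cluster number at resolution 0.5. The deposited counts were checked: the sum over genes and the number of detected genes matched the metadata exactly in 1629 of 1629 cells. The lowest UMI count of a cell was 500 and the highest deposited mitochondrial percent was 7.49%. Each cell was assigned to its sample through the library name in the metadata.

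The gene lists, cell type markers, naming rule and the alternatives named first below were fixed before the data were examined; how a cluster was scored on the markers was not. The cell class was built on the authors' deposited clusters and on marker lists for 21 cell types, of which the mast cell list had no value. A cluster was called fibroblast-like when at least 3 of the 8 fibroblast markers reached 50 CPM, no other cell type had more markers than fibroblasts among its 10 leading genes by fold (20 CPM added to both sides), and its cells' median UMI count was at least 33.3% of that of their library. Of 9 clusters, 7 met this. UMI counts were summed over the 1120 control and 282 wound cells of the class (5337160 and 1408571 UMIs), divided by the class total and scaled to CPM. Log2 ratios used a pseudocount of 0.5 counts. Sums have exact Poisson intervals, ratios the conditional exact (Clopper-Pearson) interval and shares of cells the exact binomial (Clopper-Pearson) interval, each at 95%. The ratio of Has1 in Xist-positive cells was also combined over clusters by the Mantel-Haenszel method, with a normal interval on the log scale. For it and for the glucocorticoid-induced median in these cells, cells were also redrawn 10000 times within each library and cluster. Limits of a list median run over its list members, as order statistics. All other intervals, save those over redrawn cells, cover counting error only. Cells are not replicates, so with 1 library per condition no p-value, standard error or count of changed genes was computed. A count of 0 was given the limit of 3 counts, which is 0.562 CPM in the control class and 2.13 CPM in the wound class.

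The level floor was 50 CPM in at least 1 library, which 3322 genes reached, with a median log2 ratio of 0.05. Named were the 12 genes with the largest ratio in each direction whose interval excluded 1 and whose ratio was at least 1.5-fold, leaving out mitochondrially encoded, ribosomal protein, hemoglobin and immunoglobulin genes, Xist and Y-linked genes; up to 4 members at the floor of each fixed list, those farthest from a ratio of 1; and, whatever their value, Pdgfra, Ptprc, Has1, Has2, Has3, Hyal1, Hyal2, Cd44, Tlr4, Dlk1, Pparg, Cebpa, Lpl, Camp, Reg3g, Il6, Cxcl1, Cxcl12 and Ccl2. The rule takes 111 genes; the 51 in the text were picked from them after their values were seen, as were the genes of clusters 3 and 8. Results for some genes that the rule takes are not reported here. For each of 22 gene lists, the median log2 ratio of members at the floor was placed among the medians of 10000 random lists of the same size, each member being replaced by a gene within 50 ranks of its mean expression; 17 lists had the 5 members needed. Clusters of the class with at least 50 cells in each library were also compared one by one. Gene coordinates are those of GENCODE release M21 on GRCm38, the assembly also called mm10.

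The sums, intervals, naming rule and list percentiles were tested on simulated data. Poisson counts were drawn from a single pooled profile for the genes of the wound against control comparison at the real class totals. In it 200 genes were changed, and 3076 genes reached the floor. Of the genes changed 2-fold, 97.0% were named with the right sign, and of those changed 4-fold 98.0%. In all 5 changed genes were missed, 4 of them under the floor in both simulated libraries. Of unchanged genes at the floor 0.139% passed the rule, and the interval held the true ratio for 95.2%. The draws held no spread between cells, clusters or animals. These shares therefore check the arithmetic for counting error alone and say nothing about error rates in the real libraries.

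Cells were further split, after the data were seen, by UMIs of Xist and of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Alternatives fixed at the start were median-of-ratios scaling, the mean of each cell's own CPM, all cells, only cells with at least 500 genes and under 10% mitochondrial counts, thinning each cell to 2000 UMIs, clusters given the same weights in both libraries (their share over both), removal of doublets called by Scrublet for each library, floors of 20 and 100 CPM, pseudocounts of 0.1 and 5 counts, and new Leiden clusterings (2000 variable genes, 20 principal components, 15 neighbours) at resolutions 0.3 and 1, and at 0.5 with another seed. The same cluster weights could not include clusters 2 and 7, which held 0 wound cells, so they used 810 control and 282 wound cells. They also weighted up the 16 control cells of cluster 5 and the 13 wound cells of cluster 0. Alternatives chosen after the data were seen were Xist-positive cells, Y-positive cells, Xist-positive cells of clusters 1 and 4, the class without clusters 2 and 7, and control cells weighted to the wound library's mix of Xist-positive and Y-positive cells. Scrublet marked 11 of 1317 control and 35 of 312 wound cells; marked cells stayed in the main values. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9.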

Results

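The series profiled single cells sorted from colon of C57BL/6J mice, 1 library from control mice and 1 library from mice with a skin wound. The cells were described by the labels as PDGFRA-positive colon fibroblasts, the stromal cells that make the connective tissue of the gut wall, and the sort used a viability stain together with antibodies to CD45, a leukocyte surface protein, and PDGFRA. The title of the series places the comparison in the question of how inflammation in one epithelium reaches another through fibroblasts and hyaluronan, a matrix polysaccharide. The deposited table held 1317 control cells with 5650707 UMIs in all and 312 wound cells with 1454565 UMIs. The median cell had 4205 UMIs and 1767 detected genes in the control library and 4784 UMIs and 1976 detected genes in the wound library. The median mitochondrial share was 3.90% and 3.25%. With 1 library per condition there was no replicate check and no test of any difference. Each interval given here is a 95% interval. It covers counting error in these libraries only, save where cells were redrawn or limits run over list members. No interval covers the spread between animals, and ratios compare the libraries, not the conditions. The number of mice behind each library and their sex are not given in the labels.

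The libraries differed in the cells they held. All 9 clusters in the deposited annotation had the 8 fibroblast markers Pdgfra, Col1a1, Col1a2, Col3a1, Dcn, Lum, Mmp2 and Pdgfrb over 50 CPM. These markers alone therefore did not separate the clusters. By the whole rule, which also uses depth and markers of other cell types, 7 (clusters 0, 1, 2, 4, 5, 6 and 7) were called fibroblast-like. The class made up 85.0% of control cells (1120 of 1317, exact binomial interval 83.0 to 86.9%) and 90.4% of wound cells (282 of 312, 86.6 to 93.4%). Within that class, most control cells lay in clusters 0, 2 and 1, and most wound cells in clusters 5, 4 and 1. Cluster 5 held 135 wound cells and 16 control cells, cluster 0 held 13 wound cells and 393 control cells, and clusters 2 and 7 held 250 and 60 control cells and 0 wound cells, which allows a share of up to 0.962% of the wound library for each. These numbers follow from genes that themselves differed between the libraries, so they describe which cells enter each sum and are not taken as a change in cell types. Cluster 3 stayed unnamed (13.0% of control and 8.33% of wound cells), because its cells had a median of 967 UMIs and macrophage and epithelial genes led it. Most of its cells still held fibroblast markers. A UMI of these was found in 92.98% of its control and 80.8% of its wound cells, at 27153 and 14305 CPM. In the same order, macrophage markers were found in 4.68% and 11.5% of its cells and epithelial markers in 6.43% and 7.69%. Cluster 8 stayed unnamed as well (1.97% and 1.28%), with Adamdec1, Wnt4 and Bmp4 beside the smooth muscle genes Acta2 and Tagln among its leading genes. Its Acta2 came mostly from 1 of its 4 wound cells, with 36 UMIs, against 6 UMIs in 3 of 26 control cells. The share of cells in a class can also be set by the sort.

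Sex-linked transcripts also differed between the libraries. Xist, the RNA transcribed from the inactive X chromosome of female cells (X, 103460366 to 103483254), had a UMI in 89.2% of control cells (87.4 to 90.8%) and in 25.3% of wound cells (20.6 to 30.5%), at 1438 and 395 CPM. After thinning every cell to 2000 UMIs the shares were 89.7% and 22.4%. Ddx3y, on the Y chromosome, stood at 4.60 CPM (3.01 to 6.74) in the control library and 128 CPM (110 to 148) in the wound library. Among fibroblast-like cells, 1054 control and 65 wound cells had a Xist UMI and none of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (Xist-positive cells), while 18 control and 147 wound cells showed the opposite (Y-positive cells). A further 2 control and 2 wound cells held both, and 46 control and 68 wound cells held neither. The kinds were unevenly spread over clusters. Of the 18 Y-positive cells in the control library, 11 lay in cluster 1 and 6 in cluster 5. In the wound library 90 of 147 lay in cluster 5. The values below are therefore given for the pooled class and, for part of them, within Xist-positive and Y-positive cells, the latter resting on 18 control cells.

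**Figure D1:**
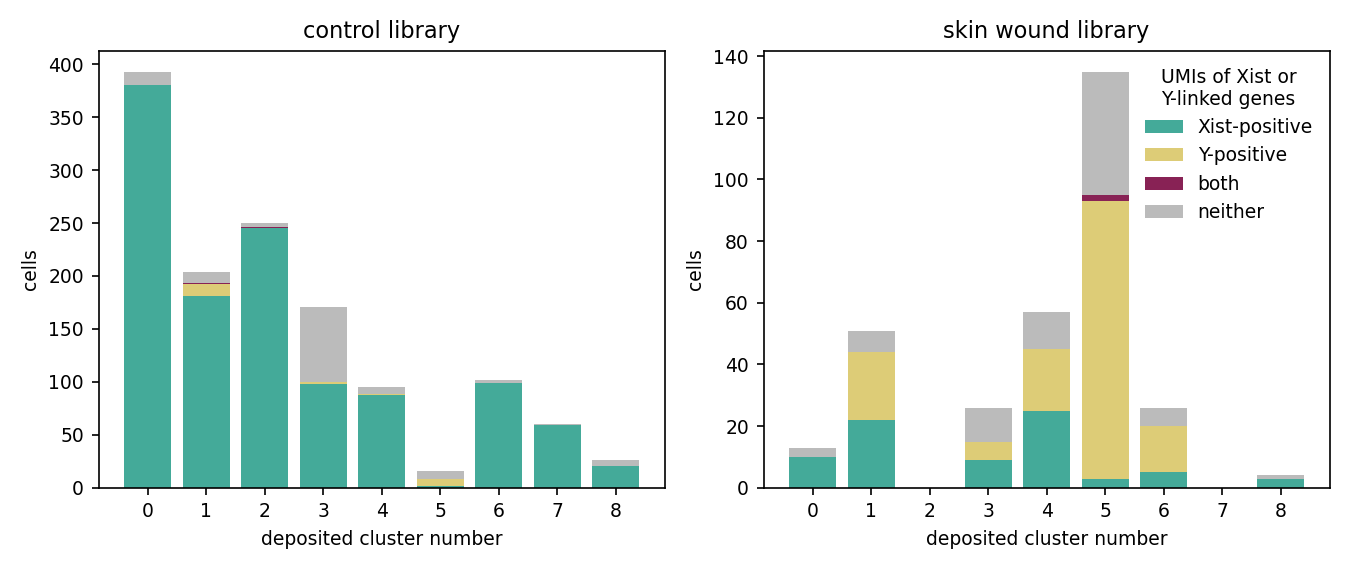
Cells per deposited cluster (x axis, cluster number; y axis, number of cells, on a separate scale for each library), coloured by whether a cell had a UMI of Xist, of the 4 Y-linked genes, of both or of neither. Clusters 2 and 7 held 250 and 60 control cells and 0 wound cells, and cluster 5 held 135 of the wound cells.

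The gate genes of the sort were read over all cells and within the class. Pdgfra is itself a marker of the class, and cluster 3, with macrophage genes in a small part of its cells, was left out of it. Values within the class are thus partly set by its definition and do not check the sort. Over all cells a Pdgfra UMI was found in 64.3% of control and 71.5% of wound cells. Over the same cells Ptprc had 29 and 18 UMIs, at 5.13 and 12.4 CPM. Pdgfra (chromosome 5, 75152292 to 75198215) stood at 322 CPM in control and 397 CPM in wound fibroblast-like cells, a ratio of 1.23 (1.12 to 1.36). It stood at 318 and 476 CPM in Xist-positive cells, but at 476 and 350 CPM in Y-positive cells (log2 ratio -0.46). With control cells weighted to the wound mix its log2 ratio was -0.18. A Pdgfra UMI was found in 70.4% of control (67.7 to 73.1%) and 75.9% of wound fibroblast-like cells (70.5 to 80.8%), at median depths of 4555 and 4939 UMIs, and in 43.7% and 56.3% after thinning to 2000 UMIs, which left out 66 and 10 cells. In cluster 3, at median depths of 1009 and 638 UMIs, the unthinned shares were 25.7% and 30.8%. Ptprc, which encodes CD45, had 0 UMIs in the fibroblast-like cells of both libraries, which allows up to 0.562 CPM in control and 2.13 CPM in wound cells, and cells with a UMI up to 0.268% and 1.06%. In cluster 3, 9 of 171 control and 3 of 26 wound cells held a Ptprc UMI. The summed blood endothelial markers stood at 42.3 CPM (37.0 to 48.2) in control and 4.26 CPM (1.56 to 9.27) in wound cells, the pericyte markers at 22.7 and 7.81 CPM, the epithelial markers at 22.7 CPM (18.8 to 27.1) and 41.2 CPM (31.3 to 53.2), and the macrophage markers at 8.81 and 10.7 CPM. Kdr, singled out after its values were seen, made up 37.1 CPM of the endothelial sum in control cells and had 0 UMIs in wound cells (up to 2.13 CPM), with 77.8 and 110 CPM in clusters 2 and 7. Of the mesothelial markers only Wt1 was in the table; it stood at 57.3 and 131 CPM, with 201 CPM in cluster 1 and 141 CPM in cluster 5 over both libraries. The summed fibroblast markers stood at 36723 CPM in control and 29367 CPM in wound cells, and those of Pi16-type adventitial fibroblasts at 9518 and 8872 CPM. In the same order, leukocyte markers stood at 1.12 and 0 CPM, T or NK cell markers at 0.937 and 0 CPM, B or plasma cell markers at 1.12 and 2.13 CPM, neutrophil markers at 0.562 and 1.42 CPM, lymphatic endothelial markers at 2.44 and 0 CPM, adipocyte markers at 2.81 and 0 CPM and erythroid markers at 0.749 and 0.71 CPM. Smooth muscle markers stood at 92.4 and 85.9 CPM, enteric glia markers at 15.9 and 18.5 CPM and those of interstitial cells of Cajal at 9.18 and 2.13 CPM. The lists for other colon fibroblasts stood at 379.98 and 388 CPM for subepithelial PDGFRA-high cells, 1333 and 1462 CPM for Adamdec1-type cells and 4427 and 4612 CPM for Grem1-type cells. The last 2 sums came almost wholly from other members of the lists, such as C3 at 2154 and 2591 CPM. Adamdec1 itself stood at 1.69 and 0 CPM and Grem1 at 4.87 and 12.1 CPM, so the sums over the class do not show such cells. By cluster, Grem1 stood at 61.5 CPM in cluster 4 over both libraries and at 0 to 5.79 CPM in the other clusters of the class. Ackr4 and Cd81 were also highest in cluster 4 within the class, while C3, Rspo3 and Ogn were higher elsewhere. Whether cluster 4 holds Grem1-type cells was not tested.

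Among all fibroblast-like cells, the estrogen sulfotransferase gene Sult1e1 (chromosome 5, 87575969 to 87591594) had the highest ratio of the genes that the naming rule takes, with 40.3 CPM (35.1 to 46.0) in control and 701 CPM (658 to 746) in wound cells, 17.4-fold higher. With the same cluster weights in both libraries, which leave out clusters 2 and 7 and weight up the 16 control cells of cluster 5, its log2 ratio was -0.68. Procr, the endothelial protein C receptor, stood at 33.7 and 256 CPM (ratio interval 6.34 to 9.14), the B cell chemokine Cxcl13 was 5.71-fold higher (4.94 to 6.62), and the small heat shock protein gene Hspb1 was 5.04-fold higher (4.32 to 5.88). Ptgs2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, was 3.90-fold higher (3.35 to 4.55), and Fkbp5, a co-chaperone of the glucocorticoid receptor, was 4.34-fold higher (3.04 to 6.20). The other 6 of the 12 genes with the highest ratios were Dmkn, Serpine2, Slc25a30, Slc10a6, Alkal2 and the long noncoding RNA gene Gm12840, with ratios of 5.28, 5.20, 4.65, 4.30, 3.92 and 4.27. Of these 12 genes, 9 were among the 10 leading genes of cluster 5. Within Xist-positive cells 11 of the 12 had a ratio over 1, and for 8 of them the interval lay above 1. Sult1e1 stood there at 2.53 and 31.3 CPM, from 13 and 10 UMIs, and Ptgs2 had a ratio of 0.80 (0.44 to 1.33). In Y-positive cells Sult1e1 stood at 415 CPM in control and 931 CPM in wound cells, from 27 and 747 UMIs. Within the control library alone, Y-positive cells thus held 164 times the Sult1e1 of Xist-positive cells (81.6 to 346). Cxcl13 went the other way there, at a ratio of 0.26 (0.0065 to 1.46), from 1 UMI in Y-positive cells. Of the control cells, 6 of 18 Y-positive and 2 of 1054 Xist-positive cells lay in cluster 5, where Sult1e1 stood at 1349 CPM over both libraries. These 2 ratios therefore cannot be told apart from a difference in clusters. Of the 65 wound Xist-positive cells, 3 lay in cluster 5, with a median of 11412 UMIs. In Xist-positive cells of clusters 1 and 4 the log2 ratios of Cxcl13, Dmkn, Slc25a30, Slc10a6, Gm12840 and Ptgs2 were -2.25, -3.34, -1.10, -1.09, -0.58 and -0.22, and Sult1e1 had 1 and 0 UMIs. Dmkn was lower in the wound library within Y-positive cells, at a ratio of 0.52 (0.30 to 0.97).

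Among the genes lower in the wound library, Pgr, the progesterone receptor (chromosome 9, 8899833 to 8968611), had 445 UMIs in control and 0 in wound fibroblast-like cells, at least 39.1-fold lower against a floor of 3 counts over the wound class. By the same floor Rxfp1, the relaxin receptor, was at least 32.9-fold lower and the phosphatase gene Ptpn5 at least 27.7-fold lower. Prlr, the prolactin receptor, was 6.99-fold lower (4.26 to 12.3). Sfrp4, a secreted WNT inhibitor (chromosome 13, 19623104 to 19632994), had the highest control level of this group, with 1092 CPM in control and 114 CPM in wound cells, 9.55-fold lower (8.17 to 11.2). Myoc was 10.8-fold lower (8.41 to 14.0), and the fatty acid binding protein gene Fabp4 stood at 96.9 CPM (88.7 to 106) in control and 7.81 CPM (3.90 to 14.0) in wound cells. Emb and Akr1c14 had 1019 and 347 UMIs in control and 3 and 1 UMIs in wound cells, with ratios of 0.011 (0.0023 to 0.033) and 0.011 (0.00028 to 0.061). Tspan13, Nfatc2 and the cadherin gene Cdh11 had ratios of 0.10, 0.16 and 0.19. Of these 12 genes, 9 were among the 10 leading genes of cluster 2 or cluster 7, the clusters with 0 wound cells. In Xist-positive cells the interval of all 12 lay below 1, and Sfrp4 stood at 1115 and 172 CPM. Clusters 2 and 7 held 304 of the 1054 control and 0 of the 65 wound Xist-positive cells. Without these clusters the log2 ratio of Myoc was 0.36, and in Xist-positive cells of clusters 1 and 4 those of Tspan13 and Cdh11 were 1.33 and 0.16. In Y-positive cells Sfrp4 stood at 30.7 CPM in control, from 2 UMIs, and 107 CPM in wound cells.

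**Figure D2:**
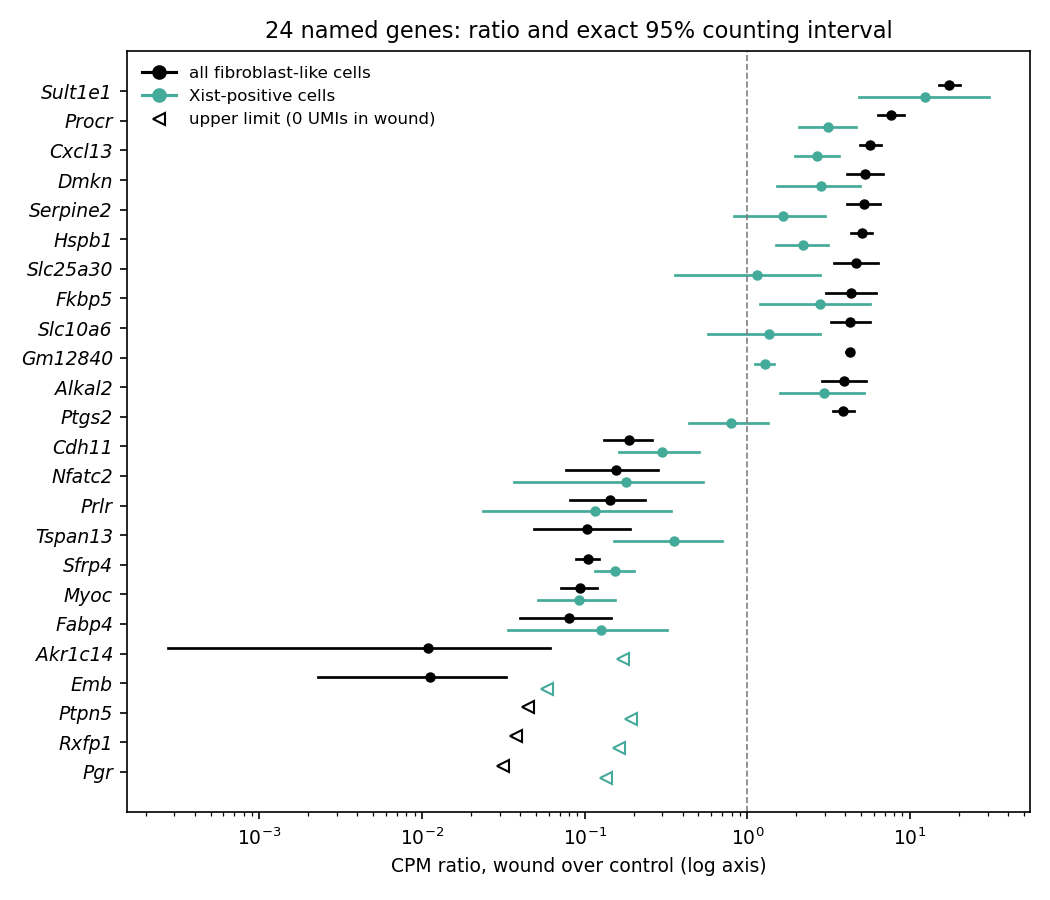
CPM ratio of the wound library over the control library (x axis, log scale) for the 24 genes farthest from 1 (y axis), in all fibroblast-like cells (black) and in Xist-positive cells (green), with exact 95% counting intervals; open triangles mark the upper limit where the wound cells had 0 UMIs. Sult1e1 lies at 17.4 in all cells, and the ratio of Ptgs2 is 3.90 in all cells and 0.80 in Xist-positive cells.

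Hyaluronan genes differed in direction. Has1, a hyaluronan synthase (chromosome 17, 17843323 to 17855205), stood at 458 CPM (440.5 to 477) in control and 864 CPM (816 to 914) in wound fibroblast-like cells, 1.88-fold higher (1.76 to 2.02). In Xist-positive cells it was lower in the wound library, at 444 and 257 CPM (ratio 0.58, 0.46 to 0.72), and in Y-positive cells it stood at 1060.4 and 1103 CPM (1.04, 0.81 to 1.35). The Xist-positive cells were spread over clusters differently: 25 of 65 wound and 88 of 1054 control cells were in cluster 4, where Has1 stood at 8.79 CPM, and 10 and 380 were in cluster 0, where it stood at 732 CPM. Compared cluster by cluster, their combined ratio was 0.64 (0.50 to 0.82, and 0.32 to 1.04 when cells were redrawn), with 0.18 (0.066 to 0.40) in cluster 1 and 0.83 (0.56 to 1.17) in cluster 0. With the same cluster weights in both libraries its log2 ratio was -0.20. Within the control library alone, Y-positive cells held 2.39 times the Has1 of Xist-positive cells (1.85 to 3.04). Of these control cells, 6 of 18 Y-positive and 2 of 1054 Xist-positive cells lay in cluster 5, where Has1 stood at 1422 CPM over both libraries. Has2, another synthase, had a ratio of 0.88 (0.72 to 1.08), and Ugdh, which makes the precursor UDP-glucuronate, was 1.36-fold higher (1.29 to 1.43) but had a ratio of 0.75 (0.65 to 0.85) in Xist-positive cells. The hyaluronan receptor gene Cd44 was 1.82-fold lower (1.43 to 2.36), and without clusters 2 and 7 its log2 ratio was 0.20. Below the level floor, the hyaluronidase gene Hyal1 had 16 UMIs in control and 14 in wound cells, a ratio of 3.32 (1.499 to 7.25), Hyal2 had a ratio of 0.77 (0.38 to 1.45), and Tlr4, an innate receptor, had 0.77 (0.45 to 1.25). Of the 8 list members at the floor, 1 was at least 1.5-fold higher, 1 at least 1.5-fold lower and 6 lay between. Their median log2 ratio was 0.05, at percentile 65.3 of 10000 expression-matched random lists, as a description of these libraries. In Xist-positive cells the median was -0.55, at percentile 0.08, and without clusters 2 and 7 it was 0.29, at percentile 99.1. Has3 was not analysed here.

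Chemokine genes differed in direction. In the pooled class Il6 was 1.85-fold higher (1.63 to 2.10) at 144 and 267 CPM, Ccl11, an eosinophil attractant, 1.77-fold higher (1.66 to 1.89), and Cxcl1, a neutrophil attractant, 1.26-fold higher (1.19 to 1.33). Ccl2, a monocyte attractant, was 1.43-fold lower (1.33 to 1.55), Cxcl10, an interferon-induced chemokine, 1.89-fold lower (1.65 to 2.18), and Cxcl12 had a ratio of 0.77 (0.66 to 0.89). Of the 11 cytokine and chemokine genes at the floor, 4 were at least 1.5-fold higher, 2 at least 1.5-fold lower and 5 between, with a median log2 ratio of 0.34 at percentile 99.8, which was -0.031 with a floor of 20 CPM and -0.36 with the same cluster weights in both libraries. The list did not keep this within kinds of cells: its median was -0.14 in Xist-positive and -0.94 in Y-positive cells. Il6 had ratios of 0.89 (0.63 to 1.23) and 0.86 (0.56 to 1.39) there, and Cxcl1 had 0.78 (0.68 to 0.89) and 0.35 (0.31 to 0.41). Ccl11 had 2.33 (2.09 to 2.60) in Xist-positive and 0.43 (0.36 to 0.52) in Y-positive cells, and Cxcl12 had 1.87 (1.54 to 2.27) and 0.43 (0.23 to 0.87). Ccl2 was lower in the wound library in both, at 801 and 175 CPM in Xist-positive cells and 1675 and 743 CPM in Y-positive cells.

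**Figure D3:**
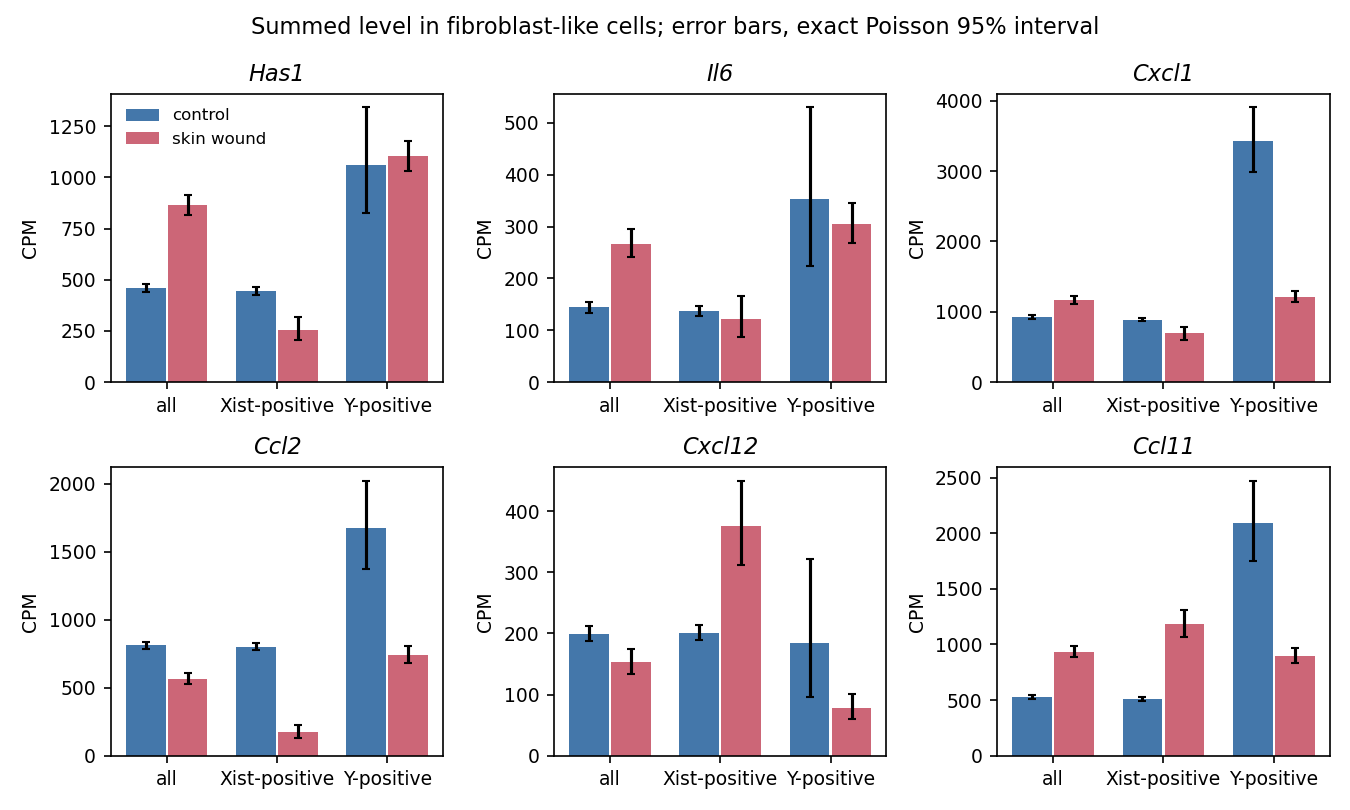
Summed CPM (y axes, from 0) of Has1, Il6, Cxcl1, Ccl2, Cxcl12 and Ccl11 in control (blue) and wound (red) fibroblast-like cells, for all cells and for Xist-positive and Y-positive cells (x axes), with exact Poisson 95% intervals as error bars. Has1 stands at 458 and 864 CPM in all cells and at 444 and 257 CPM in Xist-positive cells.

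Among the genes that glucocorticoids induce, 6 of the 11 at the floor were at least 1.5-fold higher in the wound library, 2 were at least 1.5-fold lower and 3 lay between. Beside Fkbp5, the transcriptional regulator gene Tsc22d3 was 2.32-fold higher (1.80 to 2.96) and the metallothionein gene Mt1 2.31-fold higher (2.24 to 2.39), at 1776 and 4111 CPM. Sgk1, a kinase gene, was 2.41-fold lower (1.95 to 3.02), but its log2 ratio was 0.35 with the same cluster weights and 0.24 without clusters 2 and 7. The median log2 ratio of the list was 0.84, at percentile 100, the highest median of the 17 lists, with limits over its members of -0.59 to 1.21. The median was 0.01 in Xist-positive cells, at percentile 66.6, and 0.28 in Y-positive cells, at percentile 94.7. It was 0.58 without clusters 2 and 7, at percentile 100. It turned to -0.52 in Xist-positive cells of clusters 1 and 4, at percentile 0.03, and to -0.13 with control cells weighted to the wound mix. Mt1 had ratios of 1.28 (1.18 to 1.38) in all Xist-positive cells and 0.87 (0.77 to 0.97) in Y-positive cells. In the same order Sgk1 had 0.25 (0.13 to 0.43) and 2.27 (0.60 to 19.2), the last from 2 control UMIs. Mt1 has a paralog of similar sequence, Mt2; the assignment of reads between them was not examined, so the Mt1 counts are taken as uncertain.

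Of 12 heat shock genes, 3 were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 ratio 0.33, percentile 99.6). The median was 0.09 in Xist-positive cells and -0.26 in Y-positive cells, at percentile 2.97, where 2 were higher and 3 lower by that margin, and it was -0.18 with control cells weighted to the wound mix. Of 8 complement and acute phase genes, 2 were at least 1.5-fold higher, among them C4b at 1.90-fold (1.60 to 2.27), and 0 at least 1.5-fold lower. In Y-positive cells C4b stood at 123 CPM in control, from 8 UMIs, and 112 CPM in wound cells. The complement median was 0.31, at percentile 99.5, and it was 0.42 in Xist-positive cells and 0.04 in Y-positive cells. It lay inside the central 95% of its random lists without clusters 2 and 7, at 0.11 (percentile 89.7), and in cluster 1, at 0.14 (percentile 93.85). Of 13 genes of NF-kB and innate signalling, 2 were higher and 1 lower by that margin, with a median of 0.29 at percentile 99.6, against 0.04 in Xist-positive and -0.41 in Y-positive cells. Of the 19 immediate early genes, 4 were higher by that margin and 0 lower (median 0.12, percentile 98.7), and the median was -0.40 in Xist-positive cells. The 6 adipogenic genes at the floor had a median of 0.35 at percentile 97.9, against 0.32 in Xist-positive cells, 0.016 in Y-positive cells and -0.34 in Xist-positive cells of clusters 1 and 4, and 0.28 without clusters 2 and 7 (percentile 96.4, inside its random lists). Among them Cebpd, a transcription factor gene, was 2.56-fold higher (2.42 to 2.71), with a log2 ratio of -0.57 in Xist-positive cells of clusters 1 and 4. The lipoprotein lipase gene Lpl was 1.38-fold higher (1.27 to 1.49), with a ratio of 0.45 in Y-positive cells, while Fabp4 was lower, as above. Below the floor, Cebpa had a ratio of 1.64 (1.07 to 2.46), Pparg 0.35 (0.12 to 0.80) and Dlk1 0.095 (0.0023 to 0.56), the last from 40 and 1 UMIs.

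Of 23 collagen and structural matrix genes, 7 were at least 1.5-fold lower in the wound library, 0 at least 1.5-fold higher and 16 between, and the median log2 ratio of -0.40 lay at percentile 0 of the random lists. The elastin gene Eln was 2.69-fold lower (2.37 to 3.07), the periostin gene Postn 2.08-fold lower (1.90 to 2.28) and the lumican gene Lum 1.90-fold lower (1.81 to 2.00). Lum had ratios of 0.88 (0.82 to 0.96) in Xist-positive and 1.39 (1.02 to 1.94) in Y-positive cells. The median was -0.27 in Xist-positive cells (percentile 0.27), and -0.36 in Y-positive cells (percentile 0). It lay inside the central 95% of its random lists once clusters 2 and 7 were left out, at -0.12 (percentile 4.64), and in Xist-positive cells of clusters 1 and 4, at -0.10 (percentile 13.8). Matrix remodelling genes had a median of 0.09 at percentile 82.7, with the gelatinase gene Mmp2 2.26-fold lower (2.04 to 2.51). The 9 genes of the TGF-beta pathway had a median of -0.25 at percentile 0.96, which was -0.43 in Xist-positive cells (percentile 0.29), -0.14 in Y-positive cells (percentile 24.5), -0.058 in cluster 1 (percentile 18.7), 0.051 in cluster 4 (percentile 49.4), -0.13 without clusters 2 and 7 (percentile 2.63) and -0.054 with a floor of 20 CPM. The 11 mitochondrially encoded genes had a median of -0.26 at percentile 0.12 and of -0.02 in Xist-positive cells. Medians inside the central 95% of their random lists were 0.12 for interferon response and antigen presentation, 0.05 for the unfolded protein response, 0.12 for glycolysis and hypoxia, -0.16 for BMP, WNT and hedgehog niche signals and -0.09 for 80 cytosolic ribosomal protein genes. In Y-positive cells the interferon median was -0.57 (percentile 0.18), that of the niche signals -0.93 (percentile 0.50) and that of the ribosomal genes 0.17 (percentile 99.94). With control cells weighted to the wound mix the interferon median was -0.40, and over all cells that of the niche signals was -0.45 (percentile 0.54). The niche median turned to 0.57 with a floor of 20 CPM, 0.017 with per-cell means and 0.022 without clusters 2 and 7.

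Too few members reached the floor for a median in 5 lists: 0 antimicrobial genes, 3 contractile genes, 3 circadian clock genes, 4 retinoid genes and 2 cell cycle genes. The antimicrobial gene Reg3g had 0 UMIs in the fibroblast-like cells of both libraries, and Camp was not analysed here.

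**Figure D4:**
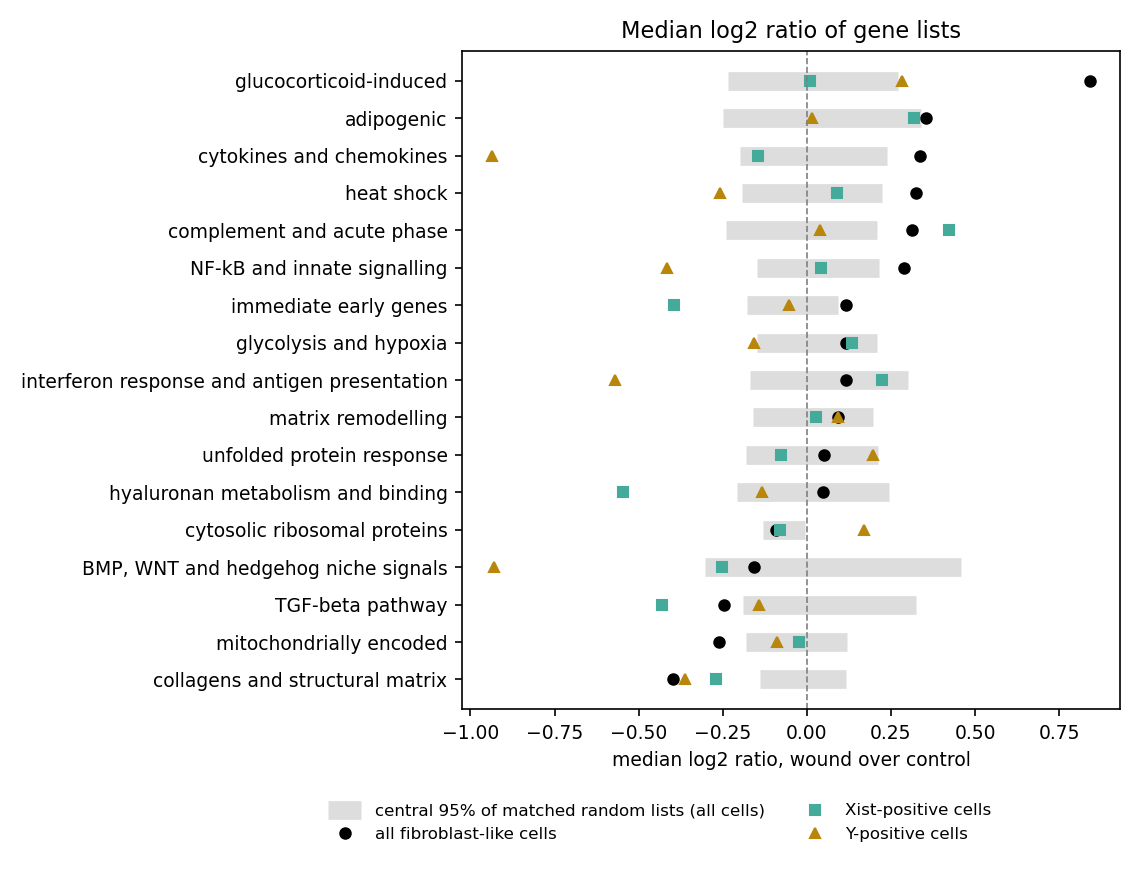
Median log2 ratio of wound over control (x axis) for each of 17 gene lists (y axis), in all fibroblast-like cells (black circles), Xist-positive cells (green squares) and Y-positive cells (gold triangles), with the central 95% of expression-matched random lists for all cells in grey. The glucocorticoid-induced list lies at 0.84 in all cells and 0.01 in Xist-positive cells.

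Clusters 1 and 4 were the 2 clusters with at least 50 cells in each library (204 control and 51 wound cells, 95 and 57 cells). The heat shock median was 0.41 in cluster 1, at percentile 99.99, and 0.52 in cluster 4, at percentile 100, with 4 of the 12 genes at least 1.5-fold higher and 0 at least 1.5-fold lower in each. In cluster 1 Hspb1 was 3.86-fold higher (2.98 to 5.01) and Ptgs2 2.80-fold higher (1.99 to 3.93). Has1 was 1.65-fold higher there (1.33 to 2.03), while in cluster 4 it was near absent, with 1 and 4 UMIs. Eln and Postn were lower in both clusters, with ratios of 0.48 (0.33 to 0.68) and 0.56 (0.46 to 0.67) in cluster 1 and 0.57 (0.44 to 0.73) and 0.57 (0.45 to 0.71) in cluster 4, whereas the collagen list's median was -0.13 in cluster 1 and 0.08 in cluster 4. The cytokine and glucocorticoid-induced medians were -0.05 and 0.19 in cluster 1 and -0.14 and 0.16 in cluster 4. Sult1e1 was 5.06-fold higher in cluster 4 (2.30 to 12.6, from 8 and 34 UMIs). The kinds of cells differed within these clusters too: in cluster 1, 181 control and 22 wound cells were Xist-positive and 11 and 22 were Y-positive, and in cluster 4 the numbers were 88 and 25, and 1 and 20. In the Xist-positive cells of both clusters together, 269 in control and 47 in wound, Has1 had a ratio of 0.135 (0.054 to 0.283, from 250 and 7 UMIs) and the heat shock median was 0.13.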

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

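The values in this part were singled out after the data were seen. For 6 of the 51 genes named, the ratio of wound over control lay on opposite sides of 1 in Xist-positive and in Y-positive fibroblast-like cells, with both counting intervals excluding 1; the difference between the kinds of cells was not tested, and the Y-positive values rest on 18 control cells. Cxcl12 had ratios of 1.87 in Xist-positive and 0.43 in Y-positive cells. Ccl11 had 2.33 and 0.43, and Lpl had 1.86 and 0.45. Dmkn had 2.84 and 0.52, and Mt1 had 1.28 and 0.87. Lum went the other way, with 0.88 and 1.39. In these comparisons the clusters differed as well, since 11 of the 18 control Y-positive cells lay in cluster 1 and 90 of the 147 wound Y-positive cells in cluster 5.

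In cluster 3, which the comparisons leave out, the enteroendocrine genes Chgb and Sct stood at 11943 and 8508 CPM in the wound library and had 0 UMIs in the control library. All 445 Chgb UMIs and all 317 Sct UMIs came from 1 cell for each gene among the 26 wound cells of the cluster.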

How the results depend on the processing

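Nothing was tested. A changed sign counts here as reversed for a gene at the level floor, at least 1.5-fold apart, whose interval excluded 1, and for a list whose median lay outside the central 95% of its random lists. A result counts as moved when it left its own interval. For a list this interval runs over its members and can be wide, as from -0.59 to 1.21 for glucocorticoid-induced genes. A list median can thus change much without counting as moved. That of glucocorticoid-induced genes went from 0.84 to 0.01 in Xist-positive cells, and that of the niche signals from -0.16 to -0.45 with all cells, and neither counted. Alternatives that split cells by Xist and Y-linked UMIs, weight them or only leave out clusters 2 and 7 were chosen after the data were seen. The same cluster weights, fixed at the start, also left out clusters 2 and 7 and weighted up cluster 5, with 16 control cells. The filter on genes and mitochondrial share kept 1119 of 1120 control and 282 of 282 wound cells of the class, so it says nothing about genes and lists. By this rule the 17 list medians neither reversed nor moved with all cells, per-cell means, thinning, removal of doublets, both pseudocounts and a floor of 100 CPM, which left 15 lists with a median. With a floor of 20 CPM the cytokine median reversed, at -0.031. Median-of-ratios scaling moved 1 list, the ribosomal one. Of the 51 genes, for which floors and pseudocounts were not varied, 0 reversed with the other settings above; 1 moved with median-of-ratios scaling, 10 with per-cell means, 2 with all cells, 13 with thinning and 3 without doublets. With the same cluster weights in both libraries 36 moved and 7 reversed, 34 and 3 in Xist-positive cells, 32 and 10 in Y-positive cells (Myoc among the 10 from 0 control UMIs), 26 and 13 in Xist-positive cells of clusters 1 and 4, 33 and 6 with control cells weighted to the wound mix, and 28 and 3 without clusters 2 and 7. At resolution 1 no counterpart of cluster 1 had 50 cells in each library, so it has no value.

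Outside this rule 7 lists and 10 genes changed sign under at least 1 setting. The hyaluronan median, 0.047 in the pooled class, was -0.0071 with median-of-ratios scaling, -0.10 with the same cluster weights and -0.056 with a floor of 20 CPM. The median of the niche signals, -0.16 in the pooled class, was 0.017 with per-cell means and 0.57 with a floor of 20 CPM, and that of the unfolded protein response was -0.0025 with median-of-ratios scaling. With the same cluster weights the log2 ratios were 0.16 for Has2, 0.86 for Hyal2, 1.04 for Tlr4, -0.23 for Lpl, -0.37 for Cxcl1 and -0.0048 for Ugdh. The other changes of sign came where cells were split or weighted by Xist and Y-linked UMIs or clusters 2 and 7 were left out.

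With the same cluster weights in both libraries, the log2 ratios were -0.68 for Sult1e1, -0.089 for Slc25a30, -0.20 for Has1, -0.42 for Il6, 0.085 for Myoc, 0.0049 for Cd44 and 0.35 for Sgk1, and the medians were -0.36 for cytokines, -0.087 for NF-kB and -0.049 for immediate early genes. Without clusters 2 and 7 they were 0.36 for Myoc, 0.20 for Cd44 and 0.24 for Sgk1. In Xist-positive cells they were -0.78 for Has1, -0.14 for Il6 and -0.28 for Ptgs2, with medians of -0.14 for cytokines and -0.40 for immediate early genes. In Xist-positive cells of clusters 1 and 4 they were -2.79 for Has1, -1.10 for Il6, -2.25 for Cxcl13, -3.34 for Dmkn, -1.10 for Slc25a30, -1.09 for Slc10a6, -0.58 for Gm12840, -0.22 for Ptgs2, -0.57 for Cebpd, -0.46 for Mt1, 1.33 for Tspan13, 0.16 for Cdh11 and 0.021 for Mmp2, with medians of -0.34 for adipogenic, -1.10 for cytokine, -0.13 for NF-kB, -0.50 for immediate early, -0.52 for glucocorticoid-induced and 0.076 for mitochondrial genes. In Y-positive cells they were -0.97 for Dmkn, 2.82 for Myoc, 1.49 for Sfrp4, 0.11 for Cd44, -0.24 for Il6, -1.23 for Ccl11, -0.21 for C4b, 0.46 for Lum, -0.21 for Mt1 and 0.87 for Sgk1, with medians of -0.94 for cytokine, -0.41 for NF-kB, -0.053 for immediate early and -0.26 for heat shock genes; the Myoc value, from 0 control UMIs, is set by the pseudocount, and the lower limit of its ratio was 0.905, while that of Sfrp4 rests on 2 control UMIs. In Xist-positive cells with control weighted to the clusters of the wound cells, they were -0.60 for Has1 and -0.033 for the glucocorticoid-induced median, the only results given this setting. With control cells weighted to the wound mix they were -0.80 for Dmkn, -0.045 for Has1, -0.23 for Il6, -0.75 for Ccl11, 0.12 for Lum and -0.13 for Mt1, with medians of -0.022 for adipogenic, -0.25 for cytokine, -0.29 for NF-kB, -0.18 for immediate early, -0.18 for heat shock and -0.13 for glucocorticoid-induced genes. The cause of these changes was not tested beyond the tests among the other observations. A gene with at most 3 UMIs in each library under a setting was given no value there.

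The fibroblast-like shares of control and wound cells were 80.9% and 81.7% at resolution 0.3, 82.7% and 93.6% at resolution 1, and 82.8% and 84.6% with another seed. At resolution 0.3 a cluster of 224 control and 53 wound cells was unnamed. It had 2 macrophage markers among its 10 leading genes, beside Iigp1 and Thbs1, which also led cluster 1. With the filter on genes and mitochondrial share the shares were 89.0% and 95.3%. The filter kept 1119 of 1120 control and 282 of 282 wound cells of the class, so these shares rose through cells lost outside it. For the other settings the cause was not tested. Thinning to 2000 UMIs put the shares of cells with a Pdgfra UMI at 43.7% and 56.3%, from fewer UMIs per cell. The floor of 3 counts was 2.13 CPM for the 282 wound cells of the class and 0.562 CPM for the 1120 control cells.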

Other observations

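The tests in this part were all chosen after the results were seen. Cluster 8, with 26 control and 4 wound cells, held genes that mark lamina propria fibroblasts: Adamdec1 stood at 2136 CPM there and at 0 to 7.30 CPM in every other cluster, and Foxf1, Foxf2 and Nkx2-3, transcription factors of gut mesenchyme, stood at 339, 187 and 292 CPM. Wnt4 and Bmp4 stood at 520 and 1703 CPM in its control cells. The adventitial gene Pi16 stood at 35.0 CPM in cluster 8 and at 627 to 6179 CPM in the clusters of the fibroblast-like class. Nkx2-3 stood at 108 CPM in clusters 1 and 4 together and at 1.55 CPM in clusters 0, 5 and 6.

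Genes of other cell types in cluster 3 came from few cells. Muc2, the mucin of goblet cells, had 405 UMIs in 1 control cell. Retnla had 365 UMIs in 3 control cells and 0 in wound cells. S100a8, a neutrophil gene, had 131 UMIs in 2 wound cells and 0 in control cells, and Il1b had 102 UMIs in 3 wound cells and 15 in 4 control cells.

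The higher Has1 of the wound library may come from its mix of cells. A rise within Xist-positive cells was not seen, at a ratio of 0.58, but is not excluded. These cells were spread over clusters differently in each library, and compared cluster by cluster their combined ratio was 0.64, with an upper limit of 1.04 when cells were redrawn, which leaves out the spread between animals. By single clusters the interval for counting error lay below 1 in cluster 1 alone, and the other clusters held 3 to 25 wound cells. Without cluster 1 the combined ratio was 0.87 (0.41 to 1.43 when cells were redrawn). With control cells weighted to the wound library's mix of Xist-positive and Y-positive cells, the ratio was 0.97, against 1.88 for the pooled class. The mix cannot be told apart from a difference in clusters or from wounding, because the control library held 18 Y-positive cells and these lay mostly in another cluster. A rise within Y-positive cells stays open for the same reason, at a ratio of 1.04 (0.81 to 1.35).

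The glucocorticoid-induced list had a median log2 ratio of 0.84 in the pooled class, with limits over its members of -0.59 to 1.21. In Xist-positive cells the median was 0.01, with an upper limit over members of 0.63. That limit was 0.27 with control cells weighted to the clusters of the wound cells. The limits over members overlap, so they do not tell these medians apart. When cells were redrawn the upper limits in Xist-positive cells were 0.24 and 0.19, under the pooled median. No limit covers the spread between animals. With control cells weighted to the wound mix the median was -0.13, which is consistent with a part for the mix of cells. Within the control library alone, the list had a median log2 ratio of Y-positive over Xist-positive cells of 0.57, at percentile 99.4. The medians of cytokine, NF-kB and heat shock genes also lay above their random lists there, at 0.85, 0.84 and 0.62. Those of complement genes (0.33) and collagens (-0.17) lay inside. These values rest on 18 Y-positive cells, of which 11 lay in cluster 1 and 6 in cluster 5, so they also hold a difference in clusters. Members of the glucocorticoid-induced list went both ways, and the control Y-positive cells were few, so neither the mix nor a rise within Y-positive cells, where the median was 0.28, can be decided.

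Clusters 2 and 7, with Pgr, Prlr and Rxfp1, held control cells alone in the deposited clustering. The cluster led by Tspan13 and Gpr83, as cluster 7 was, held 2 wound cells at resolution 0.3, 2 at resolution 1 and 1 with another seed. For counting error alone, the low number of Xist-positive cells in the wound library is argued against as the cause. Clusters 2 and 7 took 304 of 1054 control Xist-positive fibroblast-like cells (28.8%, 26.1 to 31.7%) and 0 of 65 in the wound library, with an exact upper limit of 5.52%. These limits treat cells as independent and leave out the spread between animals, whose number is not known. The wound library's Xist-positive cells are also unlikely to be control cells assigned to the wrong library, since 18.7 cells of clusters 2 and 7 would then be expected among them, and 1 cell barcode was found in both libraries. Stroma from outside the gut wall in the control library stays open, because Nkx2-3 stood at 0.52 CPM in clusters 2 and 7 but was also low in clusters 0, 5 and 6. A difference between animals in hormonal state, or an effect of wounding, was not tested.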
